A study of Mus musculus with 6 samples.

How the data were processed

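RNA-seq was done on NK cells sorted from mouse spleen, with 3 control and 3 FUS libraries, and the groups were taken from the titles and treatment labels. Per the labels' protocols, RNA was extracted with TRIzol and its integrity was checked on a Bioanalyzer. The extract protocol and the series text name different versions of the VAHTS Universal library kit, and which was used is not settled here. Per the submitters' processing notes, HISAT2, HTSeq, DESeq2 and R 3.2.0 were used with the mm10 build, without a stated order or role.

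The authors deposited 2 tables with the same 35415 genes, FPKM values per library, a fold ratio, an unadjusted p-value and a call. The tables differ only in the call, which uses at least 2-fold in one and at least 1.5-fold in the other. The FPKM unit is not named in the tables and was inferred from the values. In both deposited files 14331 genes are blank in every library and 21084 have values. There were 0 unused columns of per-library values. Counts were not among the files used here, but the values of each gene are whole multiples of a step, and whole reads were recovered for 18784 genes, 100% of the genes above 0 in at least 2 libraries, within 0.001 reads of a whole number. In simulated data the recovery returned 95.45% of genes exactly and 100% up to a common factor, so a gene's recovered reads can be off by such a factor. The depth was 31227888 to 33229018 reads per library.

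The design fixed before the data were examined named a count test for counts and limma for FPKM, and since the files hold FPKM, limma was used. limma 3.58.1 in R 4.3.3 was run with a trend on log2(FPKM + 1) of the 10945 genes with a mean of at least 1 FPKM, two-sided, with Benjamini-Hochberg adjustment at 0.05. On data simulated at the real spread of these 10945 genes, with 200 genes changed, 52.5% of changes of 1 on the log2 scale, 92.5% of changes of 2 and 96% of changes of 3 were recovered, with 4, 7 and 13 false calls. The simulated noise was independent between genes and libraries, whereas genes of the real libraries moved together, so these shares may not hold for the real comparison. The median SE of a log2 fold change was 0.181.

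Before the data were examined, 39 gene lists were fixed, covering NK cell states, pathways and markers of other spleen cells, and 4 gene families were defined. Of the list entries, 873 matched a gene symbol, 1 matched through a synonym and 18 did not match. The 40 lists and families with at least 5 measured members were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over the 40. Genes were named by a rule fixed before the data were examined: up to 10 genes per direction past the threshold, of which there were 0, then per list described up to 4 members by smallest p, and 13 fixed genes. Coordinates are those of GRCm38, the assembly of the mm10 build, from a RefSeq gene table joined by the Entrez identifiers in the files.

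Annotation terms of 10 to 500 tested genes, as the deposited tables give them, were tested with a one-sided hypergeometric test against the 10945 genes. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for tables and matplotlib 3.10.9 for figures. Libraries were compared pairwise, and the chi-square of recovered reads per degree of freedom was 32.3 to 156.8, so no pair was a repeated library. The alternatives were other scalings, tests, filters and pseudocounts, a replicate block, each library left out, genes of other cell types left out, and another threshold. A fit without control replicate 1 and FUS replicate 2, and 3 marker lists of other tissues and granulocytes, were added after the data were seen. edgeR and DESeq2 were not run here, a choice made because the deposited values are FPKM and not counts. The recovered reads served only for depth, the comparison of libraries, the test of carry-over and the limma-voom alternatives, although a count test on them was possible.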

Results

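The series holds RNA-seq libraries of natural killer (NK) cells, the innate lymphocytes that kill tumour and infected cells without prior sensitisation, taken from mouse spleens. Cells carrying CD45 and NK1.1 and lacking CD3 were sorted from the spleen, with a stated purity above 90%. There were 3 libraries under control and 3 under stimulation with focused ultrasound (FUS), which concentrates sound energy from outside the body on a chosen tissue, and the title of the series places the work in cancer immunotherapy. The single comparison the labels give is FUS against control, which asks how the transcriptome of spleen NK cells differed after the treatment. The genotype label reads wild type for the control libraries and repeats the treatment for the FUS libraries, so the genotype of the latter is not stated. Nothing in the labels says that the replicates came from separate animals, so the p-values below measure the spread between these libraries, which may be partly technical. Whole reads recovered from the deposited FPKM values numbered 33229018, 31227888 and 31988002 in the control libraries and 32053554, 31266827 and 32216628 in the FUS libraries. Values are FPKM, given as mean ± SD with n = 3 per group, and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

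NK cell markers were abundant in both groups. Gzma, a granzyme of the cytotoxic granule, stood at 1657 ± 501 FPKM in control and 1452 ± 327 in FUS, and Ncr1, which encodes the activating receptor NKp46, at 405 ± 75.7 and 314 ± 215. Ptprc, which encodes CD45, stood at 798 ± 46.9 and 729 ± 117 FPKM, and Cd3e, a T cell receptor component excluded by the sort, at 75.9 ± 21.8 and 54.4 ± 10.9. FUS replicate 2 stood apart from the other libraries. Its Pearson correlation with them over genes lay between 0.928 and 0.939, against 0.967 to 0.982 for every other pair, and the first principal component, with 59.1% of the variance of the 500 most variable genes, separated it from the rest. Its Ncr1 was 78.3 FPKM, against 335 to 499 in the other 5 libraries.

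No gene differed between FUS and control by the limma test over all genes, while adjustment of the authors' p-values left 118 higher and 29 lower. Among gene groups, granulocyte genes were called higher and type I interferon and MHC class II genes lower by camera with a preset correlation, and each of these calls was lost with an estimated correlation (adjusted p = 0.734 with an estimated correlation for each). Camp, the antimicrobial peptide cathelicidin of neutrophil granules, went from 2.76 ± 2.03 to 25.2 ± 15.9 FPKM, and S100a8, a subunit of calprotectin, from 75.3 ± 57.8 to 276 ± 140. Ifit3, an interferon-induced antiviral gene, was 9.09 ± 2.43 in control and 4.15 ± 1.21 in FUS, H2-Ab1, a chain of the MHC class II molecule, 155 ± 66.5 and 57.7 ± 19.97, and Nusap1, a mitotic spindle protein, 13.4 ± 3.86 and 5.14 ± 1.0335. By limma with Benjamini-Hochberg adjustment, 0 of 10945 genes had an adjusted p under 0.05, and the lowest adjusted p was 0.81. At an unadjusted p under 0.05 there were 399 genes higher and 231 lower, 630 in all, where chance alone gives about 547. Median-of-ratios scaling moved that split to 298 higher and 324 lower. The FUS libraries lay all above or all below the control libraries in 12.2% of genes, 856 above and 474 below, against 10% by chance. limma-voom on the recovered reads also called 0 genes, with 367 higher and 219 lower at an unadjusted p under 0.05. With 3 libraries against 3, an exact permutation test of a single gene cannot go below p = 0.10.

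Of the 40 gene lists and families tested, 3 were higher and 14 lower by camera with a preset correlation of 0.01. None of these calls held with an estimated correlation, where the lowest adjusted p was 0.734, or by fry, which asks whether a list's genes moved on balance one way and gave a lowest adjusted p of 0.824. In the limma test over all genes 0 members of any list passed, and the members that passed did so adjusted over the list alone.

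**Figure D1:**
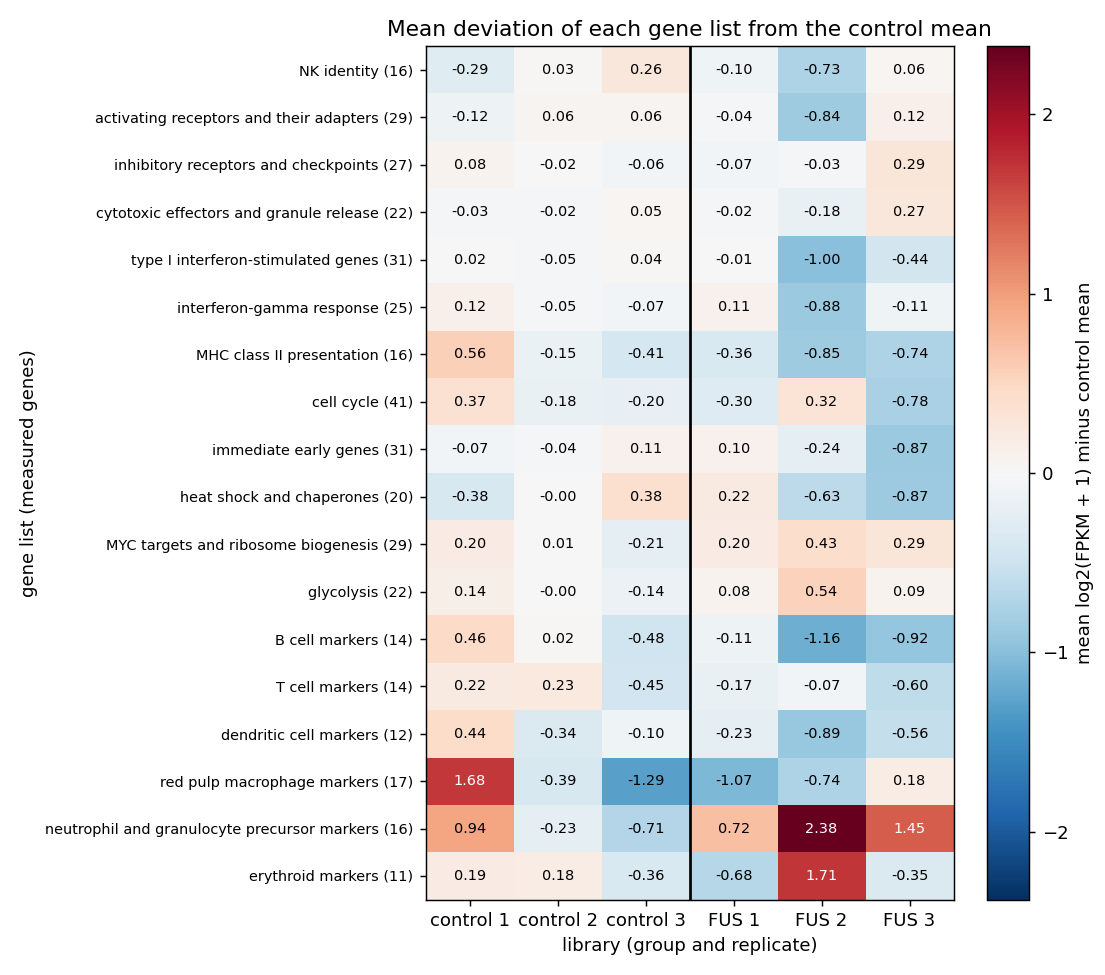
Mean deviation of each gene list from the control mean, in log2(FPKM + 1) units, per library (columns, 3 control and 3 FUS libraries) and list (rows, with the number of measured genes). FUS 2 holds the lowest value of the NK identity list, -0.73, and of the type I interferon list, -0.996, and the highest of the neutrophil list, 2.38.

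Neutrophil and granulocyte precursor markers were the list with the largest median, 1.87 on the log2 scale, and all 16 measured members had a positive fold change. Adjusted over the list alone, 9 of the 16 rose and 0 fell, with an adjusted p of 7.93e-09 for the list by camera and an adjusted p = 0.734 with an estimated correlation. Camp (Entrez 12796, GRCm38 chromosome 9, 109847377 to 109849456) rose by 2.76 ± 0.52 (log2 fold change and SE, limma adjusted p over the list alone 0.0144). Ltf, the iron-binding lactotransferrin, rose by 1.87 ± 0.51, S100a8 (chromosome 3, 90669071 to 90670034) by 1.995 ± 0.55, and Elane, neutrophil elastase, by 1.94 ± 0.58, each with a limma adjusted p over the list alone of 0.0350. Elane was listed at 0 in control replicates 2 and 3. The count over the list alone was 0 without control replicate 2, control replicate 3 or FUS replicate 3, and 1 without FUS replicate 2, where the median was 1.46. The score of the list was higher in each FUS library than in control replicates 2 and 3, and control replicate 1, at 0.94, lay above FUS replicate 1, at 0.72.

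Type I interferon-stimulated genes had a median log2 fold change of -0.40, with 30 of 31 measured members negative. Adjusted over the list alone, 3 fell and 0 rose, with an adjusted p of 1.48e-12 by camera and an adjusted p = 0.734 with an estimated correlation. Cmpk2, a mitochondrial nucleotide kinase induced by interferon (chromosome 12, 26469117 to 26479837), went from 7.11 ± 1.24 to 3.77 ± 0.456 FPKM and fell by 0.76 ± 0.17. Ifit3 (chromosome 19, 34583119 to 34588982) fell by 0.97 ± 0.24, and Ifi27l2a fell by 1.15 ± 0.29, each of the 3 with a limma adjusted p over the list alone of 0.0475. The score of the list was -0.996 in FUS replicate 2, -0.44 in FUS replicate 3 and -0.01 in FUS replicate 1. Without FUS replicate 2 the median was -0.13. Without FUS replicate 1 the median was -0.68 and the count over the list alone was 9, and it was 0 without any other single library. The interferon-gamma response list had a median of -0.30, with 22 of 25 members negative and 0 passing, and an adjusted p = 0.795 with an estimated correlation. Ciita, the master regulator of MHC class II genes, was 4.23 ± 1.47 in control and 2.26 ± 0.681 FPKM in FUS. Without FUS replicate 2 the call of that list was lost, with a median of 0.07, and without FUS replicate 1 the median was -0.55. By voom with sample quality weights the interferon-gamma call was also lost, with a median of -0.08, and the type I interferon median was -0.24.

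MHC class II presentation genes had a median of -0.66, with 15 of 16 members negative, an adjusted p of 2.46e-09 by camera and an adjusted p = 0.734 with an estimated correlation. Adjusted over the list alone, 2 fell: H2-Oa (chromosome 17, 34092379 to 34095234), a subunit of the peptide-loading modulator H2-O, by 0.86 ± 0.18, and H2-Ab1 (chromosome 17, 34263227 to 34269418) by 1.39 ± 0.32, each with a limma adjusted p over the list alone of 0.0243. Cd74, the invariant chain, was 494 ± 208 in control and 239 ± 75.2 FPKM in FUS. The count was 10 without control replicate 3, 8 without FUS replicate 1, and 0 without FUS replicate 2 or FUS replicate 3, where the medians were -0.58 and -0.68. Without control replicate 1 the median was -0.45. The score of the list was 0.56 in control replicate 1 and -0.41 in control replicate 3. It was -0.36, -0.85 and -0.74 in FUS replicates 1, 2 and 3. Markers of the cells that carry these molecules also had negative medians. B cell markers had a median of -0.75, with 14 of 14 members negative, 0 passing adjusted over the list alone, and an adjusted p = 0.734 with an estimated correlation. Ms4a1, which encodes CD20, was 29.5 ± 10.5 and 14.2 ± 8.67 FPKM, and Cd79a, a chain of the B cell receptor, 80.7 ± 26.7 and 48.7 ± 13.5. Without FUS replicate 2 the log2 fold change of Ms4a1 was -0.71 in place of -1.09. The B cell count over the list alone was 8 without control replicate 3 and 12 without FUS replicate 1. The B cell median was -0.52 without FUS replicate 2 and -0.55 without control replicate 1. The B cell score of FUS replicate 1, -0.11, lay above that of control replicate 3, -0.48. In 0 of the 14 members did every FUS library lie below every control library. Dendritic cell markers had a median of -0.57, with 10 of 12 negative and 0 passing, and an adjusted p = 0.734 with an estimated correlation. Without control replicate 1 the dendritic cell call was lost, with a median of -0.23, and without control replicate 2 there were 4 members passing over the list alone.

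Cell cycle genes had a median of -0.15, with 33 of 41 members negative, an adjusted p of 7.78e-06 by camera and an adjusted p = 0.795 with an estimated correlation. Adjusted over the list alone, 2 fell: Nusap1 (chromosome 2, 119618298 to 119650165) by 1.21 ± 0.22 and Stmn1, the microtubule-destabilising stathmin (chromosome 4, 134468320 to 134473843), by 1.15 ± 0.22, each with a limma adjusted p over the list alone of 0.0209. Mki67, the proliferation marker Ki-67, was 25.6 ± 7.59 in control and 13.02 ± 3.77 FPKM in FUS, with a log2 fold change of -0.93 ± 0.27 (limma adjusted p 0.81 over all genes). The score of the list was -0.30 in FUS replicate 1, 0.32 in FUS replicate 2 and -0.78 in FUS replicate 3. The list call was lost without FUS replicate 3, with a median of 0.02, and the median without control replicate 1 was also 0.02. The median was -0.57 without FUS replicate 2, -0.26 without control replicate 2 and -0.25 without control replicate 3, and 0 members passed without control replicate 1, control replicate 2, FUS replicate 2 or FUS replicate 3. The median was -0.24 by voom, and by voom with sample quality weights it was -0.46 and 7 members passed over the list alone.

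**Figure D2:**
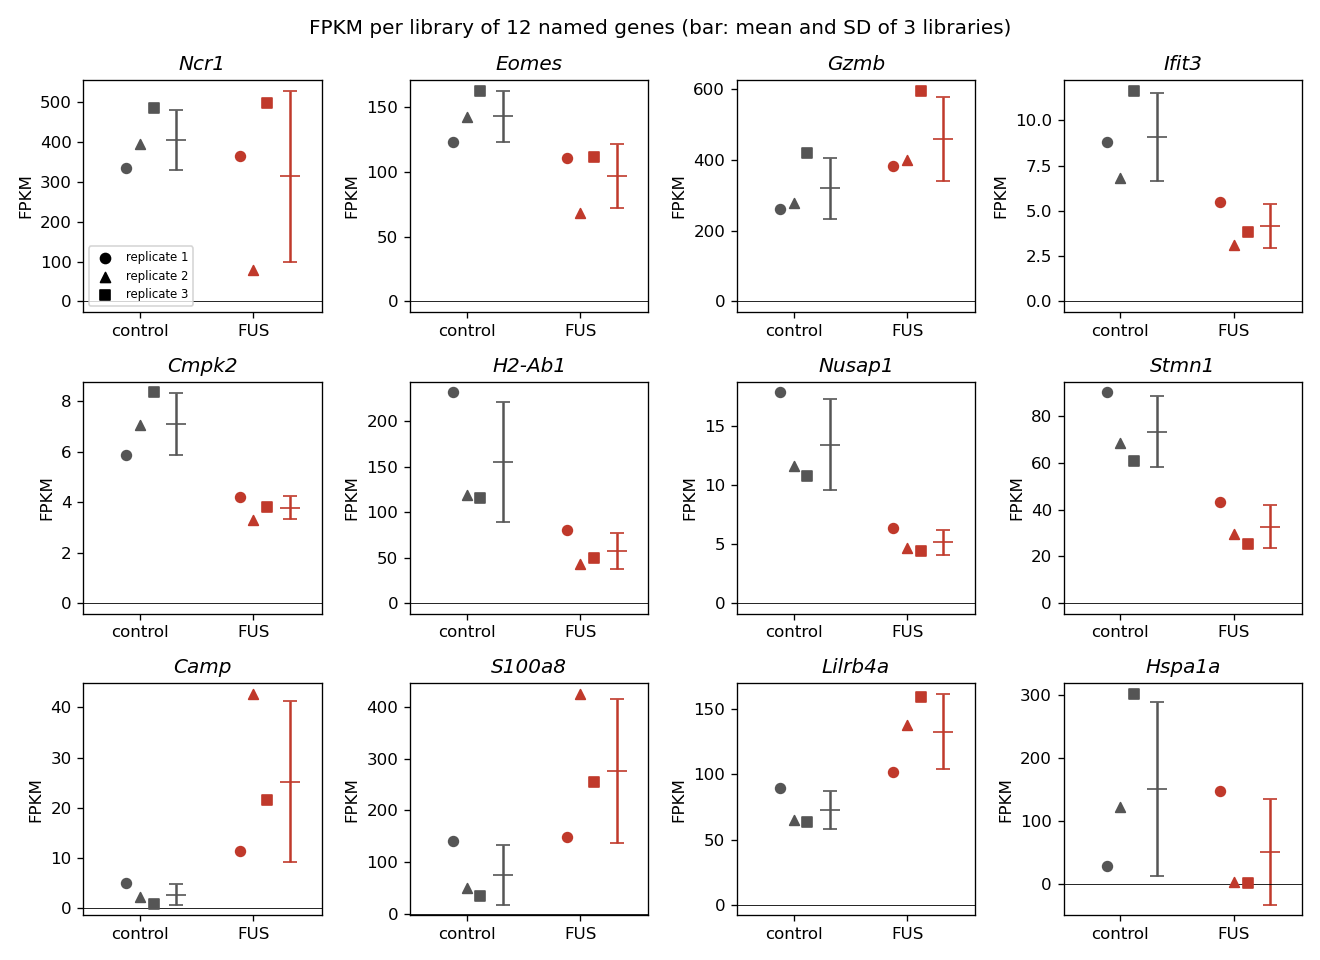
FPKM of 12 named genes in each library (points, shaped by replicate number), by group on the horizontal axis, with the mean and SD of 3 libraries beside them. Nusap1, Stmn1, H2-Ab1, Ifit3 and Cmpk2 lie lower in all FUS libraries than in any control library, while Hspa1a ranges from 1.76 to 301 FPKM.

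NK identity genes and activating receptors were lower on average in the FUS group, and FUS replicate 2 carried most of that difference. The NK identity list had a median of -0.22, with 15 of 16 members negative, 0 passing adjusted over the list alone, and an adjusted p = 0.795 with an estimated correlation. The call was lost without FUS replicate 2, with a median of 0.03, and without control replicate 3, with -0.14, and by voom with sample quality weights, with -0.09, and the median was -0.35 without control replicate 1. Eomes, a transcription factor of NK cell maturation, was 143 ± 19.6 and 96.6 ± 24.9 FPKM, a log2 fold change of -0.58 ± 0.21 and the smallest p of the list. Tbx21, which encodes T-bet, was 106 ± 22.6 and 86.8 ± 29.5 FPKM, Klrb1c, which encodes NK1.1, 333 ± 56.5 and 287 ± 84.9, and Klrk1, which encodes NKG2D, 287 ± 52.3 and 275 ± 66.6. Without FUS replicate 2 the log2 fold change was -0.35 for Eomes, -0.00464 for Tbx21 and -0.02 for Klrb1c. Activating receptors and their adapters had a median of -0.25, with 24 of 29 negative, 0 passing and an adjusted p = 0.763 with an estimated correlation, and the call was lost without FUS replicate 2, with a median of 0.01, while the median was -0.38 without control replicate 1 and -0.13 by voom with sample quality weights. Sh2d1a, the adapter SAP, was 47.0 ± 3.89 in control and 34.6 ± 5.47 FPKM in FUS.

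Cytotoxic effectors and granule release genes had a median of -0.06, with 10 of 22 positive and 0 passing either way. Gzmb, granzyme B, was 319 ± 86.6 in control and 459 ± 119 FPKM in FUS, with a log2 fold change of 0.52 ± 0.24, and Serpinb9, an inhibitor of granzyme B, 54.5 ± 17.6 and 80.2 ± 8.03. Without FUS replicate 3 the log2 fold change of Gzmb was 0.32. Prf1, perforin, was 168 ± 55.7 and 157 ± 45.5 FPKM. Ifng, the main NK cell cytokine, was 391.8 ± 62.3 and 354 ± 92.7 FPKM. Inhibitory receptors and checkpoints had a median of -0.004, with 13 of 27 positive and 0 passing adjusted over the list alone, where the lowest adjusted p was 0.0903, and 1 passed without control replicate 1 and 3 without FUS replicate 1. Their smallest p values belonged to Lilrb4a, at 72.8 ± 14.7 and 133 ± 28.8 FPKM, Klrb1b, at 147 ± 22.2 and 265 ± 79.7, and Tigit, at 19.99 ± 6.02 and 59.0 ± 39.7. Tigit was 102 FPKM in FUS replicate 2, and without that library its log2 fold change was 0.82 in place of 1.32.

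Immediate early genes had a median of -0.39, with 27 of 31 negative, 0 passing adjusted over the list alone, and an adjusted p = 0.734 with an estimated correlation. Rgs1, a regulator of G protein signalling, was 983 ± 92.6 in control and 721 ± 84.7 FPKM in FUS, Jun 492 ± 91.0 and 308 ± 117, and Cd69, an early activation marker, 319 ± 42.1 and 257 ± 119. The list call was lost without FUS replicate 3, where the median was -0.16, and without FUS replicate 1 the median was -0.62 and 11 members passed over the list alone. The heat shock list passed neither camera test over the 6 libraries, and its adjusted p was 0.154 by camera, but it was called lower without control replicate 1, with a median of -0.34, and without FUS replicate 1, with -0.41. Its inducible members varied widely within both groups: Hspa1a was 29.5, 122 and 301 FPKM in the control libraries and 148, 3.86 and 1.76 in FUS replicates 1, 2 and 3. MYC targets and ribosome biogenesis genes had a median of 0.26, with 26 of 29 positive, 0 passing adjusted over the list alone, and an adjusted p = 0.734 with an estimated correlation. The median was 0.16 without control replicate 3. Srm, spermidine synthase, was 12.6 ± 4.05 and 21.8 ± 5.15 FPKM. Glycolysis genes had a median of 0.19, with 18 of 22 positive, 0 passing and an adjusted p = 0.795 with an estimated correlation, and that call was lost without FUS replicate 2, with a median of 0.09, without control replicate 3, with 0.10, and by voom with sample quality weights, with 0.12.

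Chemokine receptor, homing and adhesion genes had a median of -0.27, with 21 of 23 negative, 0 passing adjusted over the list alone, and an adjusted p = 0.734 with an estimated correlation, and that list call was lost without FUS replicate 2, with a median of -0.09. That median was -0.46 without FUS replicate 1, -0.42 without FUS replicate 3 and -0.13 by voom with sample quality weights. Sell, the lymph node homing receptor L-selectin, was 293 ± 27.4 in control and 203 ± 50.4 FPKM in FUS, and its log2 fold change of -0.56 was -0.34 without FUS replicate 2. MHC class I presentation genes, whose products display peptides to T cells and engage inhibitory NK receptors, had a median of -0.17, with 15 of 22 negative, 0 passing and an adjusted p = 0.827 with an estimated correlation, and the call was lost without FUS replicate 2, with a median of 0.05, without control replicate 2, with -0.13, and by voom with sample quality weights, with -0.05, and the median was -0.28 without FUS replicate 3. Neither oxidative phosphorylation, ribosomal protein, NF-kB, hypoxia, apoptosis, p53 nor unfolded protein response genes passed by camera, and the medians of these lists lay between -0.10 and 0.07, but ribosomal protein genes were called lower without control replicate 3, with a median of -0.07, and NF-kB genes without FUS replicate 1, with -0.20. Mechanosensitive and calcium channel and NFAT genes had a median of -0.12, with 17 of 25 negative, and passed neither test. That list holds channels that respond to membrane stretch or let calcium into the cell, and calcium signalling genes such as Ppp3ca and Camk4.

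The authors' deposited table holds a fold change and an unadjusted p for 18888 genes and calls 535 genes up and 241 down at a p under 0.05 and at least 2-fold. In the authors' deposited table, 1262 genes had a p under 0.05, where chance gives 944.4, and Benjamini-Hochberg adjustment applied here to those p-values left 118 genes higher and 29 lower. Of the 776 calls at 2-fold in the authors' deposited table, 503 had a mean under 1 FPKM and did not enter the limma test. FUS replicate 2 was the highest library in 453 of the 535 genes called up in the authors' deposited table, and FUS replicates 1 and 3 both lay above every control library in 291 of them. Nusap1, H2-Ab1 and Stmn1 were among the genes called down in the authors' deposited table, with folds of 0.373, 0.362 and 0.435. Their p-values there, Benjamini-Hochberg adjusted here, were 0.000209, 0.00065 and 0.00128. By the same adjustment Camp, at 0.000106, and Mki67, Cd74, Ifit3, Cmpk2, H2-Oa, Lilrb4a and Klrb1b were also under 0.05. S100a8, at 0.42, was not, nor were Ltf, Tigit, Ifi27l2a, Eomes, Cd79a, Gzmb and Ncr1. Spp1, which encodes osteopontin and was chosen after its values were seen, had a fold of 2.05 in the authors' deposited table, with 9.56, 8.72 and 9.78 FPKM in the control libraries and 19.5, 17.0 and 23.02 in the FUS libraries.

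Annotation terms could not be tested on genes past the adjusted threshold by limma, since there were 0. Among genes at an unadjusted limma p under 0.05 and at least 1.5-fold, 147 higher and 124 lower, 14 terms passed for the higher genes and 43 for the lower genes of 4240 tested. Extracellular space led the higher genes, with 30 genes where 5.83 were expected, and cysteine-type endopeptidase inhibitor activity followed with 8 of 19 term genes, 6 of them stefins and related cystatins, then cornified envelope with 7 of 17, peptide cross-linking with 6 of 13 and antimicrobial peptides with 7 of 22. Those same 6 genes were all of the peptide cross-linking hits and, with S100a9, all of the cornified envelope hits, so these terms are not separate findings. The MHC class II protein complex led the lower genes, with 7 of its 11 genes. Many of the other lower terms rest on the same H2 genes, such as H2-Aa, H2-Ab1 and H2-Eb1. The terms rest on genes that did not pass the adjusted limma test. The hypergeometric test also treats genes as independent, while the MHC class II list had an estimated correlation between genes of 0.64.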

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

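By limma 0 genes passed the adjusted threshold in any setting, but every setting was a limma fit. Benjamini-Hochberg adjustment of the authors' p-values left 118 genes higher and 29 lower, so calls over all genes differed between that comparison and limma. The genes entered also differed, 18888 there against 10945 in limma, so the difference cannot be credited to the test alone. Counts adjusted over the list alone also depended on the processing. The 9 neutrophil, 3 type I interferon, 2 MHC class II and 2 cell cycle genes were 7, 0, 9 and 2 by voom. They were 10, 0, 6 and 7 by voom with sample quality weights, and 6, 0, 8 and 3 with the replicate block. With a pseudocount of 0.1 they were 9, 0, 2 and 2, and with a mean of at least 5 FPKM 8, 3, 7 and 2. Without a filter the count was 0 in each list. At an unadjusted p under 0.05 the 630 genes, 399 higher and 231 lower, became 1010, 610 and 400 without a filter on low values, and 417, 274 and 143 with a mean of at least 5 FPKM. Leaving out single libraries gave 306 to 1050 genes, with 177 higher and 129 lower without control replicate 2, and 709 higher and 341 lower without FUS replicate 1. Adding at least 1.5-fold to the unadjusted p left 271 genes, 147 higher and 124 lower, but 122 higher and 152 lower with median-of-ratios scaling. Gene lists called higher numbered 2 without control replicate 3 and 4 without control replicate 1, and lists called lower 9 without FUS replicate 2 and 15 without FUS replicate 1. Without genes of other cell types and immunoglobulins 30 lists were tested and 9 were lower, which are the 14 less the 5 lists of other cell types that were taken out. By camera with an estimated correlation 0 lists were higher and 0 lower, and by fry 0 and 0. In the authors' deposited table an adjusted p under 0.01 left 69 genes, and 57 annotation terms passed on genes at an unadjusted p under 0.05 and at least 1.5-fold. The replicate number as a block gave 300 genes higher and 207 lower. In deviations from the group means, no library correlated best with that of its own number in the other group. Medians or fold changes turned direction in at least 1 setting for 26 of 40 lists and 7 of 88 named genes. Where the median kept its direction, the camera test with the preset correlation weakened for 11 lists and became stronger for 5. A call lost along with a turn, such as that of activating receptors without FUS replicate 2, was counted as a turn only. A DESeq2 Wald test was not run, a choice made because the deposited values are FPKM and not counts. It was not ruled out, since the recovered reads served as counts for limma-voom. Scaling by library size alone was not run apart, because FPKM is already divided by the total.

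Values that turned direction are medians of lists or log2 fold changes of genes. With median-of-ratios scaling the turned values were apoptosis regulators -0.0104, cytokine receptors and JAK-STAT -0.0389, mitochondrially encoded genes -0.0144, cytosolic ribosomal protein genes -0.0376, nuclear-encoded oxidative phosphorylation -0.0401 and unfolded protein and integrated stress response -0.0306. With a mean of at least 5 FPKM the turned values were apoptosis regulators -0.0154, cytokine receptors and JAK-STAT -0.00454, inhibitory receptors and checkpoints 0.0727 and adrenergic and cholinergic receptors 0.088. By voom with sample quality weights the turned values were cytotoxic effectors and granule release 0.034, histone genes -0.0685, cytosolic ribosomal protein genes -0.00158, inhibitory receptors and checkpoints 0.0239, ILC1-like and TGF-beta imprinted markers -0.10 and erythroid markers -0.29. In the same fit they were plasma cell markers -0.14, Prf1 0.11 and Klrk1 0.0392. Without control replicate 1 and FUS replicate 2, a choice made after the data were seen, the turned values were cytotoxic effectors and granule release 0.0576, hypoxia response -0.0199, interferon-gamma response 0.0917, inhibitory receptors and checkpoints 0.0915, mechanosensitive and calcium channels and NFAT 0.00321 and MHC class I presentation 0.0281. In the same fit they were NF-kB pathway 0.0999, cytokines and chemokines 0.16, erythroid markers -0.28, red pulp macrophage markers 0.41, monocyte markers 0.13 and Fcna 0.14. By voom the turned value was histone genes -0.15. With a pseudocount of 0.1 the turned value was histone genes -0.15. Without genes of other cell types and immunoglobulins the turned value was inhibitory receptors and checkpoints 0.00853. Without a filter the turned values were adrenergic and cholinergic receptors 0.00705 and monocyte markers 0.21.

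With single libraries left out, the lists and genes that turned direction had these values. Activating receptors and their adapters ran from -0.38 without control replicate 1 to 0.00943 without FUS replicate 2. Apoptosis regulators ran from -0.0191 without FUS replicate 3 to 0.0509 without control replicate 1. Cytokine receptors and JAK-STAT ran from -0.11 without FUS replicate 3 to 0.0609 without FUS replicate 2. Cytotoxic effectors and granule release ran from -0.13 without FUS replicate 3 to 0.0621 without FUS replicate 2. Histone genes ran from -0.0718 without control replicate 2 to 0.12 without control replicate 1. Mitochondrially encoded genes ran from -0.10 without FUS replicate 1 to 0.12 without control replicate 2. Cytosolic ribosomal protein genes ran from -0.0682 without control replicate 3 to 0.0744 without control replicate 1. Interferon-gamma response ran from -0.55 without FUS replicate 1 to 0.0736 without FUS replicate 2. Inhibitory receptors and checkpoints ran from -0.12 without FUS replicate 3 to 0.0725 without FUS replicate 2. Mature (CD11b high) NK markers ran from -0.42 without FUS replicate 3 to 0.055 without FUS replicate 2. MHC class I presentation ran from -0.28 without FUS replicate 3 to 0.0546 without FUS replicate 2. NF-kB pathway ran from -0.20 without FUS replicate 1 to 0.0272 without FUS replicate 2. Cytokines and chemokines ran from -0.17 without FUS replicate 3 to 0.0256 without FUS replicate 2. NK identity ran from -0.35 without control replicate 1 to 0.0301 without FUS replicate 2. Nuclear-encoded oxidative phosphorylation ran from -0.0236 without control replicate 3 to 0.0575 without control replicate 1. P53 targets ran from -0.12 without control replicate 1 to 0.0541 without FUS replicate 3. Cell cycle ran from -0.57 without FUS replicate 2 to 0.0248 without FUS replicate 3. ILC1-like and TGF-beta imprinted markers ran from -0.0669 without control replicate 2 to 0.195 without control replicate 1. Unfolded protein and integrated stress response ran from -0.0187 without control replicate 3 to 0.15 without FUS replicate 2. Erythroid markers ran from -0.47 without FUS replicate 2 to 0.81 without FUS replicate 1. Red pulp macrophage markers ran from -1.315 without control replicate 3 to 0.20 without control replicate 1. Monocyte markers ran from -0.16 without control replicate 3 to 0.23 without control replicate 1. Plasma cell markers ran from -0.0639 without control replicate 3 to 0.47 without FUS replicate 3. Ncr1 ran from -1.24 without FUS replicate 3 to 0.0916 without FUS replicate 2. Prf1 ran from -0.30 without control replicate 1 to 0.16 without FUS replicate 2. Gzma ran from -0.40 without control replicate 1 to 0.0457 without control replicate 3. Klrk1 ran from -0.25 without FUS replicate 3 to 0.0968 without FUS replicate 2. Cd69 ran from -0.74 without FUS replicate 1 to 0.0077 without FUS replicate 3. Csf1r ran from -1.48 without control replicate 3 to 0.0266 without control replicate 1. Fcna stood at -1.80 without control replicate 3, and cytosolic ribosomal protein genes at 0.0789 without control replicate 1 and FUS replicate 2.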

Other observations

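The tests of carry-over, of dilution, of FUS replicate 2 alone as the source of the granulocyte genes, of depth, and of the low genes of the inner ear list were chosen only after the result was seen. Red pulp macrophage markers had a score of 1.68 in control replicate 1 and -1.29 in control replicate 3, with an adjusted p = 0.827 with an estimated correlation, and their list call, with a median of -0.58, was lost without control replicate 1, with 0.20, without FUS replicate 1, with -0.38, without FUS replicate 2, with -0.57, and at a mean of at least 5 FPKM, with -0.29. Their median was -0.88, -1.315 and -0.92 without control replicate 2, control replicate 3 and FUS replicate 3. T cell markers had a median of -0.27, with 13 of 14 negative and an adjusted p = 0.763 with an estimated correlation, and that list call was lost without FUS replicate 3, with a median of -0.10. It was -0.46 without control replicate 3 and -0.41 without FUS replicate 1. Erythroid markers had a score of 1.71 in FUS replicate 2 and between -0.68 and 0.19 elsewhere. Fkbp5, a glucocorticoid-induced co-chaperone, was 31.6 ± 6.04 in control and 66.8 ± 28.2 FPKM in FUS.

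Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 630 genes and the highest other split 697, and 2 of the 10 splits gave as many as the real one. For gene lists by camera the real split gave 17 and the highest other 20, with 7 of the 10 splits giving as many. By limma 0 genes passed the adjusted threshold in the real split and at most 0 in any other, so 10 of the 10 splits gave as many.

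FUS replicate 2 held 53 genes above 5 FPKM and at least 8 times the level of any other library, where no other library had such a gene, among them Rhox5 at 138 and Krt8 at 30.7 FPKM, both chosen after their values were seen. The 53 genes stood at a median of 5.81% and 4.87% of that level in FUS replicates 1 and 3, against 0.88%, 0.99% and 1.02% in the control libraries, though single genes such as Fbp2 and Mmp14, chosen after their values were seen, did not lie above every control library there. A list of 44 genes of non-haematopoietic cells, written before its values were seen, had FUS replicate 2 as the highest library in 22 of the 29 genes above 1 FPKM in any library. Some of the 29, such as Yap1 and Tead1, were above 1 FPKM only in FUS replicate 2, so the filter fixed them as hits. Of those above 1 FPKM elsewhere, Cnn3 and Itga6, for example, were also highest there, while Itgav and Gpc1 were not. Cells or RNA of a non-haematopoietic cell type may be present in FUS replicate 2, which that count alone cannot decide. The sort on CD45 selects against such cells. Carry-over of that library into FUS replicate 1 at a common share is argued against by 2 of 50 genes, Fbp2 and Wfdc2, that have 0 to 2 reads where 10 or more were expected, a bound only just reached. Dilution as the whole cause of the lower NK genes is argued against by a ratio of 2.26 between the spread of the NK identity ratios in FUS replicate 2 and that between FUS replicates 1 and 3. That argument is weak, since the ratio lay not far above its bound. The spread also rests in part on Ncr1, at 0.18 of the level in FUS replicates 1 and 3, and Nfil3, at 1.6. The cell type, a response of these cells to FUS, and how the genes came to be in FUS replicates 1 and 3 stay open.

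The fixed neutrophil list scored 2.38 and 1.45 in FUS replicates 2 and 3 and 0.72 in FUS replicate 1, below control replicate 1 at 0.94. Genes written before their values were seen had a median log2 ratio of 0.85 over the 23 genes above 0 in both groups, which is consistent with granulocytes or their RNA among the sorted cells. That median was 0.40 without FUS replicate 2, over the 20 genes above 1 FPKM in any library it was 0.74, or 0.29 without FUS replicate 2, and FUS replicate 1 was lower than control replicate 1 in 18 of the 23. Not all of the 23 lay outside the lists fixed earlier. Sell and Ly6c2 belonged to other fixed lists, and stood at 145 to 325 and 182 to 291 FPKM over the 6 libraries. FUS replicate 2 alone is argued against by the median of 1.46 of the fixed neutrophil list without it, but only for that list, in which the pattern was first seen. The genes written beforehand fell from 0.85 to 0.40 without that library, so for them FUS replicate 2 alone stays open. A larger depth is argued against by a ratio of reads of 0.99. The sort on NK1.1 selects against granulocytes, but a stated purity above 90% leaves room for a small share of other cells. The B cell gene Cd79a, for 1, stood at 80.7 FPKM in control. A real difference in granulocytes after FUS was not tested and stays open.

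Some genes known from the inner ear and nerve were lower in control replicate 1 than in the other 5 libraries, among them Ptgds, at 2.95 FPKM against 22.04 to 44.1, and Coch, at 0.77 against 7.92 to 12.3, both chosen after their values were seen. RNA from another tissue beside 5 of the 6 libraries was tested on further genes written before their values were seen, 34 of 35 with values, and the summed FPKM in control replicate 1 was 0.96 of the lowest other library, above the bound set beforehand to argue against it. Mbp and Gjb2 gave 86.6% of that sum, and their high level would hide the loss of a small share. The sum was therefore taken to decide nothing, a judgement made only after its result was seen. The explanation stays open. Of the 18 low genes of the same list, control replicate 1 was lowest in 12, but that selection was made after the values were seen and cannot count in its favour. Lower depth is argued against by a ratio of reads of 1.04, and no biological explanation was tested.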
